A study of Mus musculus with 25 samples.

How the data were processed

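The series holds 25 mouse samples. RNA libraries of 4 sensitive and 4 resistant tumours and of ASZ001 cells (3 with vehicle, 3 with CCG-1423, 3 with vismodegib) were analysed. The 8 exome samples, 4 sensitive and 4 resistant, were not analysed here. Tumour RNA was purified with Qiagen RNeasy kits per the labels. Whether replicates are separate animals or cultures is not given in the sources used here, so the p-values measure only the spread between these samples, which may be technical. Sensitive tumours 1 to 3 had Y-linked reads and sensitive tumour 4 had none, so it was no repeat of them. Any pair of samples within a group differed by a chi-square per degree of freedom of 13.5 to 184 in the tumours and 1.84 to 40.9 in the cells, where counting noise alone gives about 1.

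The signal values in both deposited tables are normalized read counts per gene, made by the authors by dividing whole read counts by 1 size factor per library, within each table separately. Each library's step was recovered from its smallest values, and 100% of values became whole reads within a tolerance of 0.01 read. TopHat, DESeq and the build mm9 are named in the submitters' processing notes with no role or version. The gene counter, the annotation and any filter on reads are not given in the sources used here. Each table lists 24015 gene symbols, of which 23988 names are shared and 22709 occur in the reference names. Genes carry symbols only, with no coordinates. Some septin and March genes had been turned into dates in the cell table. Igf2os and Igf2, and Sorbs2os and Sorbs2, overlap by name on opposite strands. Strandedness is not given in the sources used here, so their reads could not be told apart.

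Reads per library are the sums of recovered reads at genes. A count of 0 allows up to 3 reads, which is 2.45 to 3.40 normalized counts in the cell libraries and 2.09 to 4.97 in the tumour libraries. Where all libraries of a group had 0 reads, the fold is given as at least the other group's mean over 3 reads in the shallowest library of the group at 0. These floors cover counting error only.

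Tests used limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with empirical Bayes moderation and a variance trend. Genes were tested where the value was at least 10 in at least 4 tumour or 3 cell libraries. P-values were 2-sided and adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. The tumour fit held 8 libraries and the cell fit all 9, which share 1 estimate of the spread. The comparisons were resistant with sensitive tumours, each compound with vehicle, and CCG-1423 with vismodegib. Fold changes are given with the SE of the fit and group means with the SD between libraries.

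A total of 40 gene lists was written down for signalling pathways, cell types, metabolism and stress. Lists with at least 3 tested members were compared with the remaining genes by camera with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The estimated correlation and fry, which asks whether a list's genes move 1 way on balance, were run beside it. Members passing are counted over all genes and adjusted over the list alone. Tumour-derived sets were drawn only from genes tested in both the tumour and the cell fit. They held the 200 of smallest p in each direction of the tumour comparison, passing or not. These sets were tested in the cell fit in the same way. The overlap of both compounds' changes was set beside 100 simulated draws of unchanged groups against the same vehicle libraries.

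Genes were named by a rule. It takes the 10 largest changes per direction among genes that passed, with a mean of at least 50 and no overlap between groups. Gm, Rik, Mir and Snor names are left out, and where fewer than 5 passed in a direction the 5 of smallest p are given as not passing. It adds up to 4 passing members of smallest p per list and 20 fixed genes in every comparison. Members of the tumour-derived sets and of the overlap were taken by smallest p. The comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined. Leaving out each tumour in turn was among these alternatives. The repeat without sensitive tumour 4 of the naming rule, the tumour-derived sets, and the estimated correlation and fry for lists was chosen after, as were the sex term, total-read scaling and thinned reads.

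The steps were tested on simulated data with genes changed 1.5-fold, 2-fold and 4-fold. In the tumour design 0%, 7.46% and 53.0% of the changed genes were recovered with 0 false calls by limma, and without sensitive tumour 4 it was 1.49%, 7.46% and 75.8% with 4 false calls. In the CCG-1423 design 85.1%, 88.1% and 98.5% were recovered with 9 false calls, and in the vismodegib design 88.1%, 92.5% and 100% with 14. A raised set of 200 genes gave a camera p of 2.1e-233 and an unchanged one a p of 0.618. Genes in these simulated sets were drawn independently of each other, so these p-values cannot judge the preset correlation. Counts in the simulated designs were likewise drawn independently for each gene, without patterns shared by many genes. The recovery rates and false calls may therefore not hold where the real tumours differ along such a pattern.

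Alternatives were another pseudocount (0.5 or 5), other filters on low values, quantile and median-of-ratios normalization, no variance trend, a robust variance, library weights, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, a replicate block, each replicate left out, and a 2-fold threshold. Values were handled with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 and plotted with matplotlib 3.10.9.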

Results

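RNA from mouse basal cell carcinomas and from ASZ001 cells, a mouse basal cell carcinoma line that the series describes as resistant, was measured by sequencing in 17 libraries. The tumours grew in mice heterozygous for Ptch, with an inducible Cre driven by keratin 14 and floxed p53, and the mice received an oral inhibitor of Smo, the receptor that switches the Hedgehog pathway on. The labels divide the tumour libraries into 4 sensitive and 4 resistant ones. ASZ001 cells were treated with vehicle, with vismodegib, a Smo inhibitor, or with CCG-1423, an inhibitor of the actin-regulated SRF coactivators MRTF, in 3 libraries each. Doses and treatment times are not given in the sources used here. Reads at genes numbered 8111252 to 11125956 in sensitive tumours 1 to 3, 14161398 in sensitive tumour 4 and 17537094 to 20014426 in resistant tumours. The vehicle libraries held 32192090 to 44017757 reads, the CCG-1423 libraries 32024887 to 41040633 and the vismodegib libraries 30455530 to 35561668. Each table lists 24015 gene symbols, and values are normalized read counts unless a log2 fold change is named.

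The tumours parted along 1 main axis of expression, which did not follow the labelled groups throughout. The first principal component took 65.9% of the variance of the tumour libraries and set sensitive tumours 1 to 3, with scores of -88.7, -98.1 and -97.9, apart from the other 5. Sensitive tumour 4, with a score of 66.0, lay among the resistant tumours, whose scores ran from 48.3 to 65.4. Its mean correlation across genes was 0.952 with the resistant tumours and 0.828 with sensitive tumours 1 to 3. Kdm5d, Ddx3y, Eif2s3y and Uty, which lie on the Y chromosome, had reads in sensitive tumours 1 to 3 and none in the other 5 tumours. Xist, the RNA of the inactive X chromosome, had 1252 to 2939 normalized counts in sensitive tumours 1 to 3 and 60771 in sensitive tumour 4, and its mean in the resistant tumours was 69723 ± 9464 (SD, n = 4). The comparison of resistant with sensitive tumours is therefore given for all 8 tumours and, beside it, without sensitive tumour 4, and in the latter every sensitive tumour had Y-linked reads and no resistant tumour had any, so that sex and group coincide completely.

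**Figure D1:**
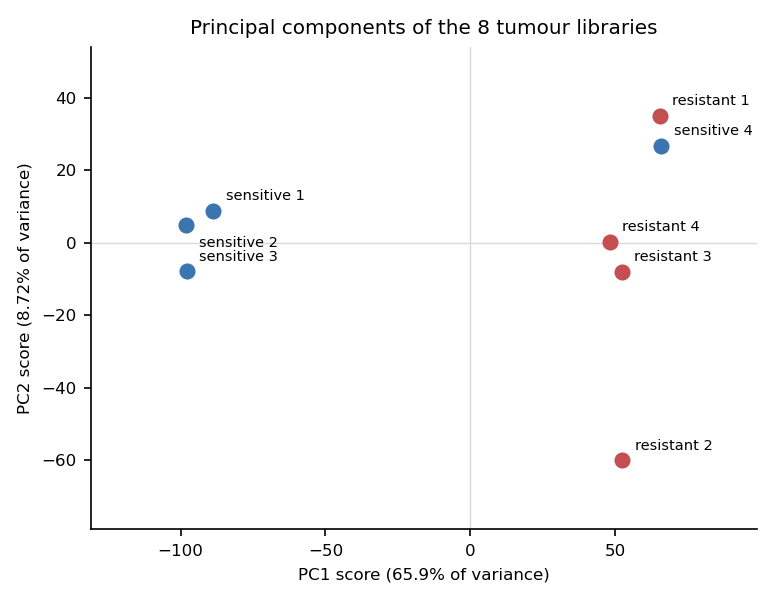
Scores of the 8 tumour libraries on the first 2 principal components of log2(normalized count + 1), with blue points for sensitive and red points for resistant tumours. The first component holds 65.9% of the variance, and sensitive tumour 4, at 66.0, lies beside the resistant tumours at 48.3 to 65.4.

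Resistant tumours were compared with sensitive ones to ask which genes mark the resistant state. With all tumours in the fit 17 genes passed, but 0 did with edgeR, a robust variance or quantile normalization, and 1638 with DESeq2. The count was also 0 with any single tumour left out other than sensitive tumour 4, without which it was 6184. A split of the tumours that mixed the labels gave 1818 genes, so chance cannot be excluded for the count of 17. Of these 17 genes 12 fell in the resistant tumours, among them Klk6 and Klk7, kallikrein proteases. These went from 1163 ± 855 to 12.8 ± 15.8 and from 3036 ± 2130 to 39.5 ± 26.5 normalized counts (SD, n = 4 each), with log2 fold changes of -6.47 ± 0.89 and -6.04 ± 0.85 (SE). Cdsn, the corneodesmosin that holds cornified cells together, fell by 4.49 ± 0.59 on the log2 scale. Abca12 (-2.75 ± 0.34), a lipid transporter of the skin barrier, Asprv1 (-2.19 ± 0.29), a protease that processes filaggrin, and Krt80 (-2.86 ± 0.39), a keratin, fell too. Klk7 alone of 16 differentiated keratinocyte genes passed, and that list had an adjusted p = 0.589 with an estimated correlation. C1qtnf3, a secreted protein related to adiponectin, rose from 70.9 ± 80.5 to 1062 ± 307 normalized counts, a log2 fold change of 4.37 ± 0.59. Uggt2, a glycoprotein folding enzyme, rose with a log2 fold change of 1.34 ± 0.17.

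Of 15076 genes tested in the 8 tumours, 17 passed, 5 of them higher and 12 lower in the resistant tumours, each with an adjusted p of 0.0488. The other named genes among them were Sorbs2os (1.85 ± 0.26), an RNA named as antisense to Sorbs2, and, on the lower side, Pglyrp4 (-4.10 ± 0.47), a peptidoglycan recognition protein, Pla2g4e (-3.47 ± 0.46), a phospholipase, Diras2 (-2.30 ± 0.27), a small GTPase, and Fam13a (-1.68 ± 0.23). Chst9, Fgf23, Gm94 and Soga3 also passed but lay outside the naming rule, and they were chosen after their values were seen. Chst9 averaged 30.1 ± 11.6 and Fgf23 31.4 ± 17.95 normalized counts in the resistant tumours, against 0.507 ± 1.01 and 0.641 ± 0.748 in the sensitive ones. Gm94 averaged 3.85 ± 2.79 against 63.8 ± 23.2 and Soga3 0.612 ± 0.826 against 20.7 ± 5.07. The higher genes of smallest p that did not pass were Sorbs2 (2.39 ± 0.36), a binding partner of actin-linked junctions, Dab2 (1.55 ± 0.25), an endocytic adaptor, Dlg2 (1.76 ± 0.29), a scaffold protein, Zfhx3 (1.95 ± 0.33), a transcription factor, and Vav3 (1.07 ± 0.18), a guanine nucleotide exchange factor, with adjusted p from 0.0641 to 0.0907.

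None of the genes given below, which were followed in every comparison, passed in the 8 tumours. Among Hedgehog genes, Gli1, the pathway's target and effector, had 2380 ± 873 normalized counts in resistant and 925 ± 703 in sensitive tumours (log2 fold change 1.53 ± 0.44, adjusted p = 0.139), and Ptch1, the receptor and target, had 2574 ± 1001 and 1027 ± 1417 (2.19 ± 0.82, adjusted p = 0.163). The log2 fold changes were 3.19 ± 1.22 for Hhip, 2.13 ± 0.65 for Gli2 and -0.37 ± 0.15 for Smo. For SRF and its coactivators they were 0.27 ± 0.19 (Srf), 0.23 ± 0.25 (Mkl1) and -0.88 ± 0.36 (Mkl2). For the cytoskeletal and secreted SRF targets they were 0.54 ± 0.47 (Acta2), 0.31 ± 0.22 (Actb), 1.03 ± 0.41 (Tagln), 0.40 ± 0.21 (Vcl), 1.78 ± 0.53 (Cyr61) and 1.54 ± 0.43 (Ctgf). Krt14, a keratin of basal cells, had -1.77 ± 0.34 (adjusted p = 0.127), Mki67, a proliferation marker, 1.95 ± 0.76, Fos 1.27 ± 0.47, Jun 0.22 ± 0.19 and Trp53 -0.21 ± 0.27. Without sensitive tumour 4 the count was 6184 of 15479 genes, and with any other tumour left out it was 0 by limma. With all 8 tumours 3789 genes had an unadjusted p below 0.05, edgeR passed 0 genes and DESeq2 1638. By limma 0 genes passed with a pseudocount of 0.5 or a robust variance.

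Among the gene lists in the 8 tumours, 17 of 37 differed from the remaining genes at the preset correlation, although members mostly did not pass singly. With an estimated correlation none of the 37 lists passed by camera (adjusted p = 0.589 for each of the 17). Ribosomal protein genes lay higher in resistant tumours (median log2 fold change 0.56, 22 of 22 positive, adjusted p = 9.5e-07), as did hypoxia and glycolysis genes (1.81, 17 of 17) and NF-kB and cytokine genes (1.90, 17 of 17), at the same adjusted p. Cell cycle genes lay higher (1.36, 31 of 32, adjusted p = 7.2e-06), and so did integrated stress response genes (0.83, 17 of 18, adjusted p = 0.000166). SRF-MRTF targets, the cytoskeletal genes that MRTF switches on, had a median of 0.45 with 30 of 37 positive (adjusted p = 0.000826). Neutrophil (2.65), interferon (1.06), extracellular protease and integrin (0.90), oxidative phosphorylation (0.47), endothelial (0.60) and unfolded protein response genes (0.38) also lay higher. Differentiated keratinocyte (-1.46), basal keratinocyte (-0.75), hair follicle progenitor (-0.41) and hair shaft and inner root sheath genes (-1.29) lay lower. Over all genes 0 members of these lists passed by limma except Klk7. Adjusted over the list alone, 16 hypoxia and glycolysis, 12 NF-kB and cytokine, 10 ribosomal protein, 8 differentiated keratinocyte, 0 SRF-MRTF and 0 Hedgehog target genes passed. Hedgehog targets had a median of 0.38 with 9 of 13 positive (adjusted p = 0.119) and Hedgehog components one of 0.05 (adjusted p = 0.611). Cholesterol synthesis (0.0798), mast cell (0.085), TGF-beta (0.085), SRF-TCF immediate early (0.0909), fibroblast (0.17), YAP-TEAD (0.176), NRF2 (0.181) and skeletal muscle lists (0.213) did not pass, with their adjusted p in brackets. Neither did heat shock (0.522), Wnt (0.526), smooth muscle (0.54), macrophage (0.611), melanocyte (0.631), p53 (0.757), Notch (0.99), sebaceous gland (0.95), T and NK cell (0.892) or B and plasma cell lists (0.99). The T and NK cell and the B and plasma cell lists had medians below 0 and means above 0 (-0.44 and 0.17, -0.01 and 0.05), and the sebaceous list a median of 0.04 and a mean of -0.01. Adipocyte, blood and mitochondrially encoded genes had fewer than 3 tested members.

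Without sensitive tumour 4, 3183 genes were higher and 3001 lower in the resistant tumours. Igf2, a fetal growth factor, rose from 546 ± 251 (SD, n = 3) to 54044 ± 11929 normalized counts (n = 4), a log2 fold change of 6.70 ± 0.30, and Igf2os, which overlaps it, by 7.05 ± 0.31. Csf3, the neutrophil growth factor, averaged 2.09 ± 2.33 in sensitive tumours 1 to 3 and 2016 ± 1248 in the resistant tumours. The neutrophil chemokine Cxcl2 had a log2 fold change of 8.06 ± 0.95, and Cxcl3 was at least 48.8-fold higher, since all of sensitive tumours 1 to 3 had 0 reads. The transcription factors Eya1 (7.66 ± 0.50), Sall3 (7.06 ± 0.42) and Pou3f4 (6.63 ± 0.81) rose, and Foxa2, at 0 in sensitive tumours 1 to 3, was at least 82.1-fold higher. Il20ra, a cytokine receptor, was at least 25.2-fold higher. On the lower side Klk6 (-7.21 ± 0.72), Klk7 (-6.83 ± 0.60), Coch (-7.64 ± 0.33), an extracellular matrix protein, and Gldn (-7.58 ± 0.55) fell, while Trim67 and Sult1c1, at 0 in every resistant tumour, were at least 70.7-fold and 148-fold lower. The Y-linked Kdm5d, Ddx3y, Eif2s3y and Uty were at least 297-fold, 214-fold, 198-fold and 177-fold lower.

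Hedgehog and SRF targets moved in both directions without sensitive tumour 4. Of 13 Hedgehog targets 6 rose and 2 fell, the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.103). Gli1 rose by 1.98 ± 0.27 on the log2 scale, Ptch1 by 3.06 ± 0.47 and Ccnd1, which encodes cyclin D1, by 2.38 ± 0.36. Among 19 Hedgehog components, 4 rose, among them Gli2 (2.89 ± 0.21), and 3 fell, among them the ligand Dhh (-2.45 ± 0.44); adjusted over the list alone 3 rose and 2 fell (adjusted p of the list 0.889). Of 37 SRF-MRTF targets 17 rose, among them Itga5 (1.62 ± 0.18), an integrin, and Cald1 (1.34 ± 0.15), which binds actin and myosin, and 3 fell, among them Csrp1 (-2.19 ± 0.26); adjusted over the list alone 20 rose and 3 fell. The list's adjusted p was 0.000483, or adjusted p = 0.38 with an estimated correlation.

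Inflammatory, hypoxia and proliferation genes were higher without sensitive tumour 4. The nuclear RNA Malat1 parted the tumours in the same way, at 2.89 to 3.20% of reads in sensitive tumours 1 to 3 and 1.30 to 1.69% in the other 5 tumours. All 17 hypoxia and glycolysis genes rose, with Vegfa, an angiogenic growth factor, at 3.52 ± 0.21 and Pgam1, a glycolytic enzyme, at 2.48 ± 0.15 (list adjusted p = 9.5e-12, and 0.38 with an estimated correlation). Of 32 cell cycle genes 28 rose, among them the replication helicase genes Mcm2 (2.22 ± 0.26) and Mcm3 (2.67 ± 0.24), with list adjusted p = 3.3e-11, and 0.38 with an estimated correlation. Of 17 NF-kB and cytokine genes 16 rose, with the chemokine Cxcl1 at 4.92 ± 0.48 and Ptgs2, which makes prostaglandins, at 4.28 ± 0.38, and this list also passed with an estimated correlation (adjusted p = 0.0469). All 10 neutrophil genes rose, with S100a9 at 4.18 ± 0.26 and S100a8 at 3.83 ± 0.25 (adjusted p = 3.0e-07, and 0.285 with an estimated correlation). The collagenase gene Mmp13 rose by 5.40 ± 0.28 and the stromelysin gene Mmp3 by 5.92 ± 0.51 among 8 proteases and integrins that rose (adjusted p = 0.000404, and 0.38 with an estimated correlation). Adjusted over the list alone these 5 counts were the same. Of 17 differentiated keratinocyte genes 8 fell, 9 adjusted over the list alone, among them Krt10 (-3.75 ± 0.33) and Krt2 (-5.40 ± 0.60), and 2 rose (adjusted p = 0.0121, and 0.483 with an estimated correlation). Of 16 basal keratinocyte genes 6 fell, among them Krt14 (-1.99 ± 0.31) and Krt15 (-3.45 ± 0.53), and 1, Itga3 (2.59 ± 0.33), rose (adjusted p = 0.069), with equal counts adjusted over the list alone. All 5 hair shaft and inner root sheath genes that passed fell, with Krt71 at -4.51 ± 0.45 (adjusted p = 0.00505, and 0.285 with an estimated correlation). Ribosomal protein (16 of 22 higher, 17 adjusted over the list alone), oxidative phosphorylation (15 of 24, 17), integrated stress response (12 of 18, 12), interferon (9 of 17, 11), cholesterol synthesis (12 of 20, 12, with 1 lower), unfolded protein response (9 of 14, 9) and endothelial lists (6 of 12, 6) also lay higher. Their adjusted p with an estimated correlation ran from 0.38 to 0.565. Of 5 melanocyte genes 3 fell (adjusted p = 0.0608), among them Dct (-4.79 ± 0.48) and Sox10 (-3.95 ± 0.69), and the endothelial receptor Flt1 (1.62 ± 0.21) and the muscle gene Tnnt3 (4.24 ± 0.58) rose. Hair follicle progenitor genes had 8 lower and 2 higher on either adjustment (adjusted p = 0.0917).

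**Figure D2:**
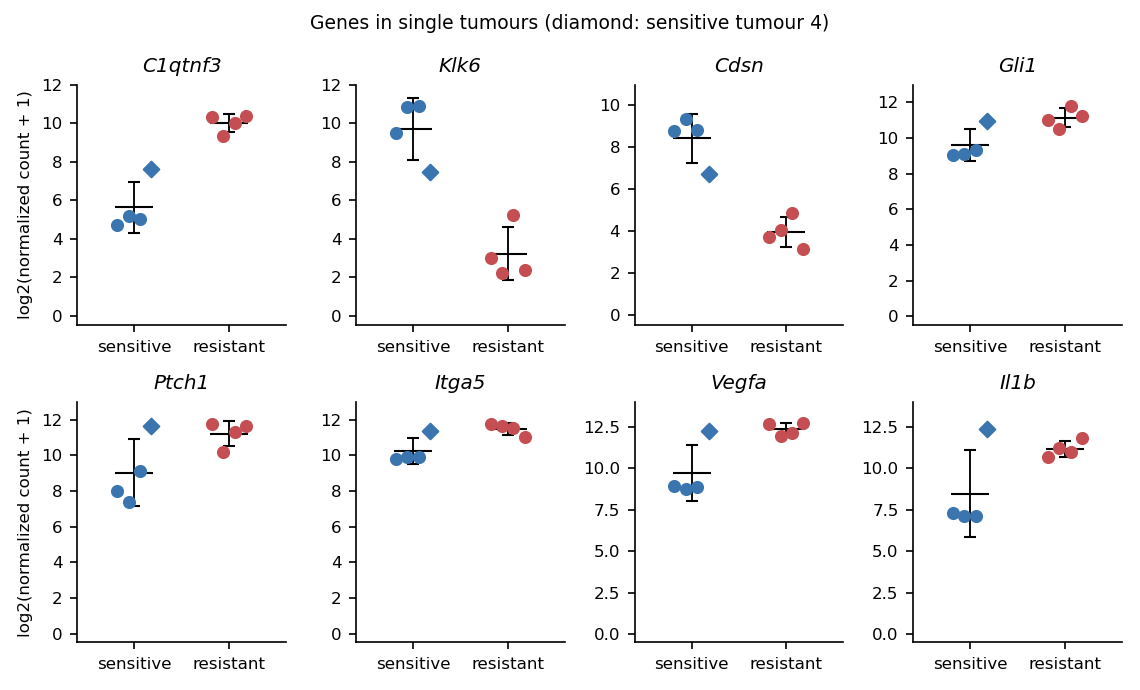
Values of 8 genes in single tumours as log2(normalized count + 1), with the mean and SD of 4 tumours per group as bars and sensitive tumour 4 as a diamond. C1qtnf3, Klk6 and Cdsn, which passed in the 8 tumours, keep all 4 sensitive tumours apart from the resistant ones, whereas for Gli1, Ptch1, Itga5 and Vegfa sensitive tumour 4 lies within the range of the resistant tumours and for Il1b above it.

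CCG-1423 was compared with vehicle to ask which genes change with it in ASZ001 cells. Whether a change runs through MRTF and SRF was not tested. Over all 12775 genes tested 5464 rose and 5437 fell, beside which the list counts below stand. Of 18 integrated stress response genes 16 rose and 2 fell (adjusted p = 0.344 with an estimated correlation). Ddit3, the transcription factor CHOP, went from 896 ± 37.7 to 10987 ± 203 normalized counts (SD, n = 3 each; log2 fold change 3.62 ± 0.04), and Trib3, a pseudokinase induced by stress, rose by 4.95 ± 0.07. Nupr1, a chromatin protein outside that list, rose by 6.34 ± 0.09. Of 16 basal keratinocyte genes 15 fell and 1 rose (adjusted p = 0.0579 with an estimated correlation). Krt14 dropped from 444824 ± 3586 to 86019 ± 1894 normalized counts (-2.37 ± 0.05), Krt5, its partner, by 2.66 ± 0.05, and Krt15 by 6.27 ± 0.08. Of 30 SRF-MRTF targets 20 fell and 8 rose (adjusted p = 0.61 with an estimated correlation), with Actb at -1.53 ± 0.04 and the tropomyosins Tpm1 and Tpm2 at -2.22 ± 0.03 and -2.10 ± 0.03. Gli1 fell by 1.72 ± 0.09 (adjusted p = 5.9e-11) while Ptch1 rose by 0.85 ± 0.09 (adjusted p = 2.3e-07).

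Of 12775 genes tested 10901 passed, 5464 higher and 5437 lower, and 3442 of them changed at least 2-fold, 1493 higher and 1949 lower. The other genes with the largest rises were Prss35 (7.24 ± 0.27), a secreted protease homologue, Car6 (5.67 ± 0.19), a secreted carbonic anhydrase, Etv5 (5.60 ± 0.16), an ETS transcription factor, and Spp1 (5.47 ± 0.15), which encodes osteopontin. Slc6a12, a betaine transporter, reached 546 ± 105 normalized counts from 1.74 ± 2.11 with vehicle, Btg4 337 ± 25.0 from 4.02 ± 0.663, Spry4, a feedback inhibitor of receptor signalling, 99.3 ± 4.35 from 0.899 ± 0.8292, Plekhs1 100.2 ± 7.64 from 1.254 ± 1.11 and Cox6a2 110 ± 14.6 from 1.38 ± 0.774. The largest falls were those of Dio2, which activates thyroid hormone (245 ± 40.4 with vehicle and 0.682 ± 0.598 with CCG-1423), Ucp2 (-6.05 ± 0.04), a mitochondrial carrier, Prlr (-5.56 ± 0.21), the prolactin receptor, Fbn2 (-5.39 ± 0.08) and Fmod (-5.37 ± 0.09), both matrix proteins, Tmem44 (-5.30 ± 0.16), Sema3d (-5.16 ± 0.11), a guidance molecule, Dsg4 (-5.08 ± 0.21), a desmosomal cadherin, and Pi15 (-4.96 ± 0.09).

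Among genes of the SRF and Hedgehog pathways, the lists moved in part. Of 30 SRF-MRTF targets 20 fell, among them Filip1l (-2.04 ± 0.03), Enah (-1.56 ± 0.03), which extends actin filaments, Ctgf (-1.58 ± 0.10), a secreted matrix signal, and Vcl (-0.59 ± 0.03), which links actin to adhesions, and 8 rose (median -0.51, adjusted p = 0.00403; adjusted p = 0.61 with an estimated correlation). Srf rose by 0.11 ± 0.04, Mkl1 rose by 0.31 ± 0.03, Mkl2 fell by 0.22 ± 0.04 and Cyr61 rose by 0.18 ± 0.08. Acta2 and Tagln were not tested, at 3.12 ± 1.45 and 0.755 ± 1.31 normalized counts with vehicle. SRF-TCF immediate early genes, which SRF drives with other cofactors, had 15 members higher, among them Atf3 (3.48 ± 0.09), Dusp1 (2.52 ± 0.08), Ier2 (1.61 ± 0.04) and Fos (1.32 ± 0.19), and 6 lower, among them Jun (-0.95 ± 0.06), with a median of 1.22 (adjusted p = 0.0351, and 0.654 with an estimated correlation). Hedgehog targets split, 4 higher and 5 lower (adjusted p = 0.617): Ccnd1 rose by 1.20 ± 0.06, while Sfrp1, a secreted Wnt antagonist, fell by 1.06 ± 0.05. Of 18 Hedgehog components 7 rose and 8 fell (adjusted p = 0.731), and Gas1, a Hedgehog coreceptor, fell by 3.88 ± 0.05, Smo by 0.42 ± 0.03 and Gli2 by 0.18 ± 0.06, while Gli3 and Boc rose by 1.14 ± 0.04 and 1.47 ± 0.06. In these and all other lists of this comparison the counts adjusted over the list alone equalled those over all genes. Hhip had 0 reads in every vehicle and CCG-1423 library and was not tested.

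Other groups moved more evenly with CCG-1423. All 24 oxidative phosphorylation genes fell, among them Uqcrc1 (-1.07 ± 0.03), a subunit of respiratory complex III, and Cox6c (-1.11 ± 0.04), with a list adjusted p of 1.7e-06, and 0.446 with an estimated correlation. Of 16 basal keratinocyte genes 15 fell (median -1.62, adjusted p = 8.4e-06, and 0.0579 with an estimated correlation), of 16 differentiated keratinocyte genes 15 fell, among them Dsg1a (-3.30 ± 0.07) and Sprr1a (-2.11 ± 0.08) (adjusted p = 0.00171, and 0.344 with an estimated correlation), and of 12 hair follicle progenitor genes 9 fell, among them Lgr6 (-4.96 ± 0.16) and Tbx1 (-3.47 ± 0.11) (adjusted p = 0.011, and 0.277 with an estimated correlation). All 3 hair shaft genes tested fell, with Tchh, trichohyalin, at -3.63 ± 0.06 (adjusted p = 0.0133, and 0.277 with an estimated correlation). Integrated stress response genes had 16 higher and 2 lower, with Mthfd2 (2.70 ± 0.04) and Atf4 (2.16 ± 0.03) among the risers (adjusted p = 8.4e-06, and 0.344 with an estimated correlation). NF-kB and cytokine genes had 12 of 14 higher, among them Icam1 (4.42 ± 0.15), Relb (2.47 ± 0.05) and Lif (2.36 ± 0.07), with adjusted p = 0.000442, and 0.277 with an estimated correlation. Of 22 ribosomal protein genes 21 rose (median 0.65, adjusted p = 9.0e-06), and of 32 cell cycle genes 26 rose, among them Aurka (1.38 ± 0.06) and Mki67 (0.86 ± 0.07), and 3 fell, among them Rrm2 (-2.39 ± 0.04), with adjusted p = 0.000442; both lists had an adjusted p = 0.617 with an estimated correlation. Cholesterol synthesis had 16 lower and 3 higher, with Mvk at -1.94 ± 0.04 (adjusted p = 0.00867, and 0.344 with an estimated correlation). Hypoxia and glycolysis had 12 lower and 3 higher, the latter being Ndrg1 (2.47 ± 0.04), Vegfa (2.32 ± 0.05) and Hk2 (1.35 ± 0.03) (adjusted p = 0.0209, and 0.617 with an estimated correlation). Unfolded protein response genes had 10 higher, among them the chaperone Hspa5 (1.57 ± 0.03), and 2 lower (adjusted p = 0.0381, and 0.504 with an estimated correlation), and heat shock genes 9 lower, among them Hspb1 (-1.97 ± 0.04), and 2 higher (adjusted p = 0.0452, and 0.617 with an estimated correlation). Interferon (adjusted p = 0.084), Notch (0.152), TGF-beta (0.309), fibroblast (0.344), protease and integrin (0.436), endothelial (0.594), skeletal muscle (0.697), YAP-TEAD (0.727), macrophage (0.812) and p53 lists (0.92) did not pass. Wnt, sebaceous gland, NRF2, smooth muscle and melanocyte lists had adjusted p = 0.617 each. The macrophage list had a median of 0.35 and a mean of -0.03, and the p53 list -0.03 and 0.90. Neutrophil, B and plasma cell, mast cell and T and NK cell genes, like adipocyte, blood and mitochondrially encoded ones, had fewer than 3 tested members. None of the 15 lists past the threshold held with an estimated correlation, and Trp53 rose by 0.53 ± 0.04.

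Vismodegib was compared with vehicle to ask what Smo inhibition changes in ASZ001 cells. Gli1 fell from 1207 ± 102 to 247 ± 22.0 normalized counts (SD, n = 3 each), a log2 fold change of -2.28 ± 0.09 (adjusted p = 1.2e-09), the largest fall among genes that passed with a mean of at least 50. Ccnd1 fell by 0.53 ± 0.06, Rasl11b, a Ras-like protein, by 0.94 ± 0.11 and Bcl2, a survival factor, by 0.28 ± 0.06, whereas Ptch1, at 320 ± 13.3 and 279 ± 10.96 normalized counts, did not pass (-0.20 ± 0.09, adjusted p = 0.248). The spread in this fit was shared with the CCG-1423 libraries, whose pairs differed by a chi-square per degree of freedom of 8.451 to 40.9. Vehicle pairs differed by 1.844 to 4.617 and vismodegib pairs by 2.266 to 3.145, so the Ptch1 result does not exclude a fall. Ptgs2 fell by 1.10 ± 0.05. Rn45s, the ribosomal RNA precursor, fell by 2.17 ± 0.14. Lars2 (-2.12 ± 0.14), a mitochondrial leucyl-tRNA synthetase, and the nuclear RNA Malat1 (-1.17 ± 0.09) fell as well. Over all cell libraries the log2 ratio of Lars2 to Rn45s had an SD of 0.0924. The fall of Lars2 may therefore be one of ribosomal RNA reads counted at that gene. Rn45s took 6.33 ± 0.466% of the reads with vehicle, 8.26 ± 1.91% with CCG-1423 and 1.49 ± 0.0978% with vismodegib.

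Of the 12775 genes 703 passed, 202 higher and 501 lower, and 35 changed at least 2-fold, 1 higher and 34 lower. The largest rises were those of Prlr (1.02 ± 0.21), the metalloproteases Mmp12 (0.98 ± 0.16), Mmp13 (0.88 ± 0.09) and Mmp3 (0.63 ± 0.07), Snx22 (0.86 ± 0.21), Pcdh17 (0.82 ± 0.13), a protocadherin, Slc5a10 (0.80 ± 0.15), a sugar transporter, Lgals3bp (0.74 ± 0.20), Fbln5 (0.62 ± 0.09), an elastic fibre protein, and Bst2 (0.62 ± 0.14), an antiviral membrane protein. Further large falls were those of Hist1h1e (-1.81 ± 0.18), a linker histone, Slc24a2 (-1.34 ± 0.18), an ion exchanger, Atp6v0a4 (-1.33 ± 0.10), a proton pump subunit, Slco4a1 (-1.33 ± 0.15), an organic anion transporter, Pi15 (-1.19 ± 0.09) and Prss22 (-1.19 ± 0.23), a serine protease. With 1 library left out the count ran from 325 to 498, being 372, 358 and 392 without vehicle replicates 1, 2 and 3 and 380 and 325 without vismodegib replicates 2 and 3, and with only the vehicle and vismodegib libraries in the fit it was 1721.

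Hedgehog targets formed the list that fell most clearly with vismodegib. Of 9 members 4 fell (5 adjusted over the list alone) and 0 rose by limma, where 2 had a positive fold change; the median was -0.20, the adjusted p 2.3e-06, and adjusted p = 0.0452 with an estimated correlation. Of 18 Hedgehog components 2 fell, Gli2 (-0.23 ± 0.06) and Gli3 (-0.15 ± 0.04), 4 adjusted over the list alone, and the list did not pass (adjusted p = 0.234). Of 30 SRF-MRTF targets 8 fell, among them Filip1l (-0.44 ± 0.03), Ctgf (-0.56 ± 0.10), Actb (-0.26 ± 0.04) and Tpm1 (-0.25 ± 0.03), or 9 lower and 2 higher adjusted over the list alone (median -0.05, adjusted p = 8.4e-05, and 0.503 with an estimated correlation). Interferon response genes lay higher, with Bst2 the 1 member that passed (2 adjusted over the list alone; median 0.47, adjusted p = 0.00124, and 0.554 with an estimated correlation). Hypoxia and glycolysis genes had 4 higher, among them Slc2a1 (0.22 ± 0.03) and Ldha (0.17 ± 0.04), and 1 lower, Hk2 (-0.35 ± 0.03), with 7 and 1 adjusted over the list alone (adjusted p = 0.00124, and 0.503 with an estimated correlation). Integrated stress response (Slc7a11, 0.41 ± 0.04), cholesterol synthesis (Mvk, 0.15 ± 0.04) and hair shaft genes (Hoxc13, 0.33 ± 0.04) each had 1 member that rose, or 4, 4 and 1 adjusted over the list alone, with adjusted p = 0.0082, 0.0209 and 0.0397, and 0.503 each with an estimated correlation. Unfolded protein response genes lay lower (median -0.04, adjusted p = 0.0446, and 0.503 with an estimated correlation), with 0 members past the threshold over all genes by limma and 3 adjusted over the list alone. The remaining 25 lists did not pass, with adjusted p from 0.0793 (YAP-TEAD targets) to 0.923. Median and mean differed in sign for cell cycle (-0.00 and 0.01), macrophage (-0.04 and 0.16), smooth muscle (0.10 and -0.05) and heat shock genes (0.02 and -0.01). SRF-TCF and hair follicle progenitor genes lay lower by the test with a median of 0.03 each. Of the remaining fixed genes Srf (-0.05 ± 0.04), Mkl1 (-0.04 ± 0.03), Mkl2 (-0.07 ± 0.04), Vcl (-0.06 ± 0.03), Cyr61 (-0.08 ± 0.08), Smo (0.08 ± 0.03), Krt14 (0.06 ± 0.05), Mki67 (0.05 ± 0.07), Fos (0.30 ± 0.19), Jun (-0.05 ± 0.06) and Trp53 (0.01 ± 0.04) did not pass.

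**Figure D3:**
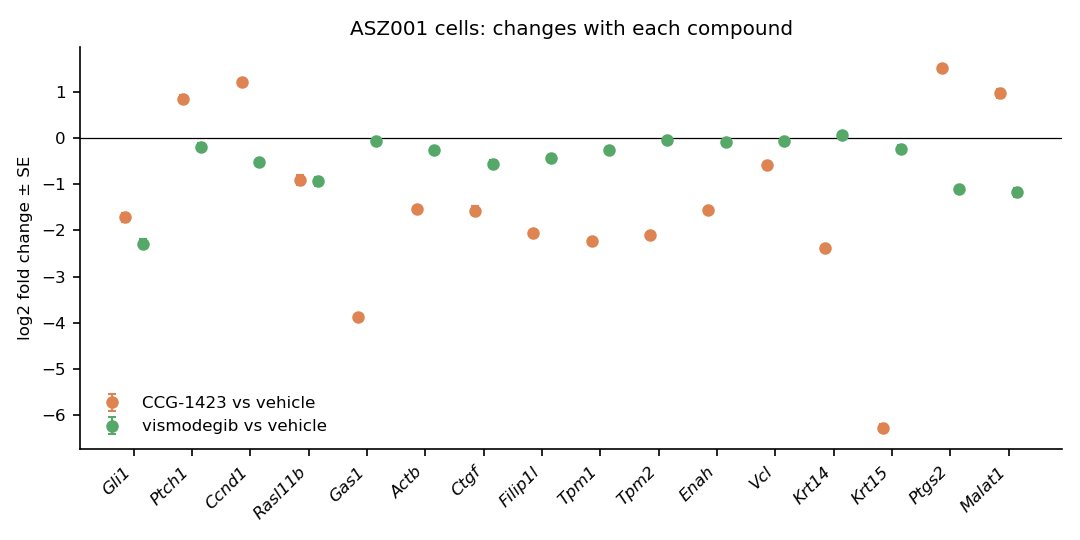
Log2 fold changes against vehicle, with SE, of 16 genes in ASZ001 cells treated with CCG-1423 (orange) or vismodegib (green), from 3 libraries per group. Gli1 lies at -1.72 and -2.28, while Ptch1, Ccnd1, Ptgs2 and Malat1 lie above 0 with CCG-1423 and below 0 with vismodegib, where Ptch1 did not pass.

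**Figure D4:**
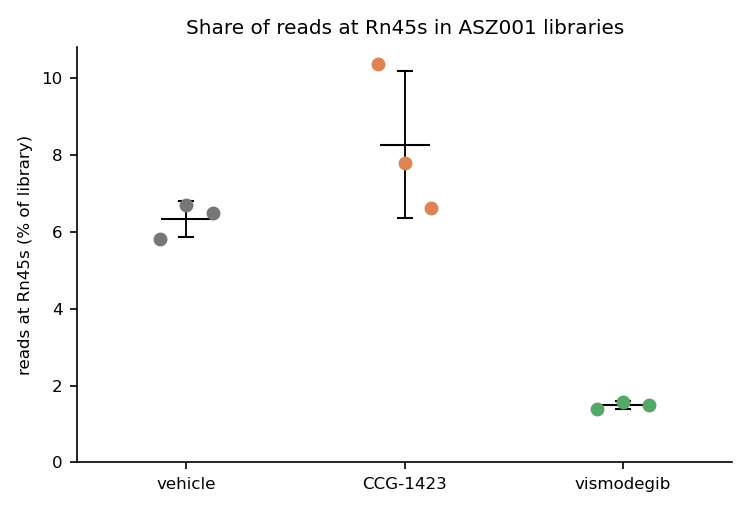
Share of each ASZ001 library's reads at Rn45s in percent, with points for the 3 libraries per group and bars for mean and SD. Vehicle averages 6.33%, CCG-1423 8.26% and vismodegib 1.49%.

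The compounds were also compared with each other, at doses and times that are not given in the sources used here. Gli1 was higher with CCG-1423 than with vismodegib by 0.56 ± 0.09 on the log2 scale (adjusted p = 3.5e-05), as were Ptch1 (1.05 ± 0.09), Ccnd1 (1.73 ± 0.06) and Ptgs2 (2.63 ± 0.05). Actb (-1.26 ± 0.04), Ctgf (-1.01 ± 0.10), Tpm1 (-1.97 ± 0.03), Krt14 (-2.43 ± 0.05) and Gas1 (-3.80 ± 0.05) were lower. Of 12775 genes 10839 differed, 5420 higher and 5419 lower with CCG-1423, and 3494 did so at least 2-fold. The largest differences were those of Slc6a12, at 546 ± 105 and 0 normalized counts and so at least 163-fold higher, Prss35 (8.09 ± 0.27), Nupr1 (6.47 ± 0.09), Spp1 (6.08 ± 0.15) and Etv5 (5.85 ± 0.16), and on the lower side Prlr (-6.57 ± 0.21), Krt15 (-6.04 ± 0.08), Kcna4 (-6.00 ± 0.30), a potassium channel, and Fmod (-5.67 ± 0.09). SRF-MRTF targets lay lower with CCG-1423 (7 higher, 20 lower; 8 and 20 adjusted over the list alone; adjusted p = 0.0104, and 0.64 with an estimated correlation). Hedgehog targets did not pass (5 higher and 3 lower on either adjustment, adjusted p = 0.741), with a median of 0.22 and a mean of -0.07. Medians and means also differed in sign for skeletal muscle (0.08 and -0.62), macrophage (0.39 and -0.19), p53 (-0.08 and 0.97) and Hedgehog component lists (0.05 and -0.13). In all 14 of 33 lists passed, and with an estimated correlation none did, the smallest adjusted p being 0.0552 for basal keratinocyte genes.

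The changes with both compounds share the vehicle libraries, which alone makes them resemble each other. Across the 12775 genes the fold changes correlated at r = 0.054, against 0.5004 ± 0.0163 for simulated unchanged groups with that vehicle, and their covariance was 0.0126 against 0.0103 ± 0.000491 in 100 simulated draws. Genes are not independent replicates, and CCG-1423 changes spread far more widely than simulated noise does. Of the 202 genes higher with vismodegib 82 were also higher with CCG-1423, where 86.4 would overlap by independence, and of the 501 lower genes 259 were also lower, where 213 would. Simulated unchanged groups shared at most 0 and 1 by limma, but unchanged groups rarely pass the threshold at all, so these say nothing about agreement beyond independence. A further 296 genes passed in opposite directions. With 10901 of the 12775 genes passing with CCG-1423, many would do so by independence, so this count is no sign of opposed effects. Lower with both were Ucp2 (-6.05 ± 0.04 with CCG-1423 and -1.06 ± 0.04 with vismodegib), Fgf5 (-1.09 ± 0.05 and -0.95 ± 0.05), a growth factor, Synpo (-2.15 ± 0.04 and -0.74 ± 0.04), an actin-associated protein, Pthlh (-1.08 ± 0.07 and -0.98 ± 0.07), a parathyroid hormone relative, and Pdgfb (-0.68 ± 0.04 and -0.52 ± 0.04). Mmp13 was higher with both (1.46 ± 0.09 and 0.88 ± 0.09). Opposite were Ptgs2 (1.52 ± 0.05 and -1.10 ± 0.05), Irs1 (0.21 ± 0.06 and -0.86 ± 0.06), an insulin signalling adaptor, Klf5 (0.85 ± 0.03 and -0.42 ± 0.03), a transcription factor of epithelia, and Malat1 (0.97 ± 0.09 and -1.17 ± 0.09).

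Genes of the tumour comparison were followed into ASZ001 cells to ask whether genes that differ between resistant and sensitive tumours move with either compound. The sets held the 200 of smallest p on each side, among genes also tested in the cells. Genes lower in resistant tumours fell with CCG-1423, 122 lower and 50 higher (median -0.48, adjusted p = 0.000622, and adjusted p = 0.0338 with an estimated correlation). Among them Krt15 (-6.27 ± 0.08), Krt14 (-2.37 ± 0.05), Ckmt1 (-2.74 ± 0.03), a mitochondrial creatine kinase, and Gpr115 (-3.18 ± 0.05) fell, and Abca12 rose by 2.62 ± 0.04. Genes higher in resistant tumours lay higher with CCG-1423, 106 higher and 64 lower (median 0.36, adjusted p = 0.0333), with Sat1 (3.03 ± 0.05), a polyamine enzyme, Vegfa (2.32 ± 0.05) and Hyou1 (1.13 ± 0.03), a chaperone, rising and the chemokine Cxcl14 (-3.52 ± 0.05) and the hypoxia factor Epas1 (-2.31 ± 0.05) falling. This second set did not pass with an estimated correlation (adjusted p = 0.218) or when built without sensitive tumour 4 (adjusted p = 0.261). With vismodegib neither set passed (adjusted p = 0.769 for each), with 14 higher and 15 lower among genes higher in resistant tumours and 6 higher and 12 lower among genes lower in them. Of the 5 higher and 12 lower genes that passed in the tumours, only 2 and 8 were in these sets, the others not being tested in the cells. Of each 200 genes 59 and 57 were also in the sets built without sensitive tumour 4.

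**Figure D5:**
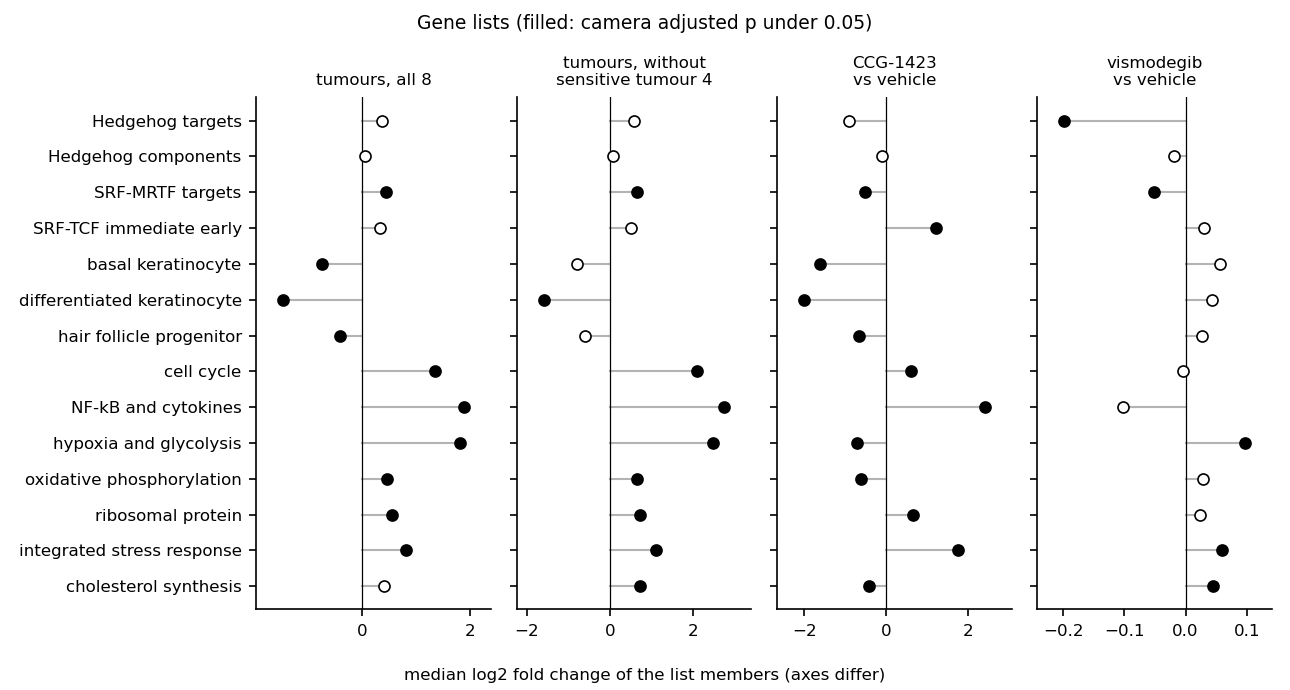
Median log2 fold change of the members of 14 gene lists in the 8 tumours, in the tumours without sensitive tumour 4, and in ASZ001 cells with each compound against vehicle; points are filled where the adjusted p was under 0.05 at the preset correlation, and the axes differ. SRF-MRTF targets lie at 0.45 and 0.65 in the tumour panels and at -0.51 and -0.05 with CCG-1423 and vismodegib.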

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

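The tests of a swap, of the sex of the animals, of scaling and of depth for CCG-1423, and of other splits of the samples, were chosen only after the results were seen.

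Of 161 groups of 4 tumour values, 32 held 1 tumour far from the other 3, with a gap to its nearest neighbour, as a share of the range, above Dixon's critical value. Of the 32, 27 concern sensitive tumour 4. Chance alone marks about 1 in 20 groups, but many of these genes were named by the rule repeated without that tumour, so this share does not hold for them and their number is no measure against chance. It was the highest sensitive tumour, with gap shares of 0.838 for C1qtnf3, 0.848 for Gli1, 1 each for Foxa2, Cxcl3, Il20ra and Chst9, 0.835 for Eya1 and 0.878 for Sall3. For genes of the cytoskeleton, replication and hypoxia these were 0.943 for Itga5, 0.888 for Tgfb1i1, 0.837 for Mcm5, 0.949 for Mcm3, 0.952 for Vegfa and 0.916 for Pgam1. For inflammatory genes they were 0.967 for Il1b, 0.880 for S100a8, 0.836 for S100a9 and 0.889 for Mmp13. Sensitive tumour 4 was the lowest for Trp53 (0.838), Kdm5d (0.945), Ddx3y (0.946), Eif2s3y (0.981), Uty (0.960), Coch (0.933), Gldn (0.833), Csrp1 (0.847) and the share of reads at Malat1 (0.838). Sensitive tumour 1 was the lowest for Jun (0.962). Resistant tumour 2 was the lowest for Jun (0.875) and Mcm3 (0.852) and the highest for Krt2 (1), and resistant tumour 1 was the highest for Ptgs2 (0.895).

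Sensitive tumour 4 lay with the resistant tumours. Thinned to equal reads, its mean correlation with resistant tumours still exceeded that with sensitive tumours 1 to 3 by 0.119, which argues against depth. A swap between both groups would leave a resistant tumour nearer to sensitive tumours 1 to 3, and the number of such tumours was 0, while a single wrong label stays open and was not tested. The sample descriptions number sensitive tumours 1 to 3 as S_RW1, S_RW3 and S_RW4 and sensitive tumour 4 as S_RW9. They give the resistant tumours as R_RW6, R_RW7, R_RW8 and R_RW10, so the numbers part sensitive tumours 1 to 3 from the rest. What the numbers stand for is not given in the sources used here. Y-linked reads parted the tumours as the first component did, with 0 tumours in disagreement, so the sex of the animals and the expression state cannot be told apart. The share of reads at Malat1, looked at after the split was seen, parted the tumours likewise, so a difference in RNA composition stays open and was not tested. Rn45s did not, with its lowest share, 2.71%, in sensitive tumour 4. A tumour that had become resistant may also explain it, and this was not tested.

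CCG-1423 changed most of the tested genes. With total-read scaling 10889 genes passed, and with reads thinned to the shallowest library 10792, against 10901. The count thus depended neither on the choice between these scalings nor on unequal depth, and depths already overlapped between the groups. Both scalings bring the libraries to a common level, so neither could show a change in total RNA per cell. A broad response of the cells to the compound may underlie the count, at a dose and time that are not given in the sources used here. That hypothesis was not tested further.

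Rn45s, Lars2 and Mir6236 fell together with vismodegib. Over the 9 cell libraries the log2 ratio to Rn45s had an SD of 0.0924 for Lars2 and 0.106 for Mir6236, against 1.19 for log2 Rn45s itself. Ribosomal RNA reads counted at all 3 in these libraries would give this. The genes were taken up because they fell together, so small ratio SDs follow in part from that choice. Within each group, shares of reads at Lars2 and Rn45s ranked the libraries in the same order. In the tumours the ratio was not constant, with an SD of 0.217 for Lars2 and 0.447 for Mir6236 against 0.448 for log2 Rn45s. This goes against ribosomal RNA reads at Mir6236 in the tumours. For Lars2 the SD lay between the bounds set for the cells and decides nothing. The other 16 mitochondrial tRNA synthetase genes had a median log2 fold change of 0.0494, which argues against a change of that class. Histone genes picked by name, whose replication-dependent members make RNA without a poly(A) tail, had a median of -0.449 ± 0.166 (SE, 29 genes). This was short of the fall set in advance for less RNA without tails, yet past the bound set against it by less than its spread. Single histone genes ran from -2.11 to 0.401, with 6 passing lower and 0 higher by limma. Less RNA without tails therefore stays open as an explanation. Loss of ribosomal RNA synthesis in the cells also stays open and was not tested. Malat1 ranked the groups as Rn45s did, with 0.0765% of reads with vehicle, 0.154% with CCG-1423 and 0.0360% with vismodegib. Whether RNA composition or the compounds moved Malat1 was not tested.

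Other splits of the samples were counted for each comparison. Chance cannot be excluded for the 8 tumours, where 3 of 35 splits, the real one with 17 genes included, gave at least 17. The others of these gave 977 and 1818. Both kept sensitive tumours 1 to 3 together, which points to a structure of the samples. Such splits did not all give large counts, with 0 where resistant tumour 1 joined them and 12 where resistant tumour 3 did. Without sensitive tumour 4, 1 of 35 splits, the real one, gave 6184 genes and the highest other 126. Leaving out each tumour in turn was planned, but this fit was singled out for splits only after that tumour was seen to lie with the resistant ones. The remaining split is also that of Y-linked reads. For both reasons this count says nothing about chance. The 10 splits of each cell comparison are too few, with 1 split, the real one, at 10901 genes for CCG-1423, 703 for vismodegib and 10839 for CCG-1423 against vismodegib, and the highest other at 0 by limma in each.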

How the results depend on the processing

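Total-read scaling, thinned reads, the sex term, and the tumour-derived sets, estimated correlation and fry without sensitive tumour 4 were chosen only after the results were seen. Of the alternatives for named genes 11373 kept their direction and side of the threshold, 349 passed newly and 489 no longer passed, and for lists 1589, 61 and 127 did so. The tumour count of 17 genes by limma, with 3789 at an unadjusted p below 0.05, was 0 with a pseudocount of 0.5, a mean of at least 50, quantile normalization, a robust variance, total-read scaling or edgeR. It was also 0 by limma with the sex term, a term for Y-linked reads, with 818 at an unadjusted p below 0.05. The group effect then rested on sensitive tumour 4 alone, the only sensitive tumour without such reads, so that count says nothing about the others. It was 4 with thinned reads, 1638 with DESeq2 and 7951 with library weights. With 1 tumour left out it ran from 0 to 6184, with 6184 without sensitive tumour 4 and 0 without any other single tumour. The labels reuse replicate numbers between groups, but deviations of equally numbered samples correlated across genes at only -0.146 to 0.122 in tumours and -0.0427 to 0.0368 in cells, and with the replicate block the tumour count was 0 by limma. The CCG-1423 count was 3442 when a 2-fold change was also required and 10619 to 10947 with 1 library left out, and the direct comparison of compounds 3494 and 10631 to 10947. The vismodegib count of 703 was 302 without a variance trend, 1655 with library weights, 1721 with only the 6 libraries compared and 35 with a 2-fold change. With 1 library left out it ran from 325 to 498, being 372, 358 and 392 without vehicle replicates 1, 2 and 3 and 380 and 325 without vismodegib replicates 2 and 3. The tumour-derived higher set with CCG-1423 had a median of 0.36 (adjusted p = 0.218) with an estimated correlation, 0.27 (adjusted p = 0.295) with sets of 100, 0.21 (adjusted p = 0.261) with sets without sensitive tumour 4, and 0.21 (adjusted p = 0.516) with both. With 1 library left out its median ran from 0.31 to 0.39 and that of the lower set from -0.57 to -0.45, and with vismodegib from -0.00466 to 0.0102 and from -0.00285 to 0.0128. The covariance of both compounds' changes was 0.0101 with a pseudocount of 5 and 0.0042 with a mean of at least 50, where the correlation was 0.0298, against 0.0059 and 0.0029 for simulated unchanged groups with those settings. Lists past the threshold numbered 17 in the tumours, 0 with an estimated correlation, 0 by fry, 1 with an estimated correlation and 24 by fry without sensitive tumour 4, and 16 to 20 with 1 tumour left out. For CCG-1423 they numbered 15, then 0 with an estimated correlation, 31 by fry and 15 to 16 with 1 library left out, and for the direct comparison 14, then 0, 31 and 13 to 15. For vismodegib they numbered 8, then 1 with an estimated correlation, 1 by fry and 3 to 8 with 1 library left out, with 3 without vehicle replicate 3. By fry, which tests another question than camera, Hedgehog targets (median 0.22) and macrophage genes (median 0.39) reversed in direction between the compounds. Sebaceous gland genes reversed by fry without sensitive tumour 4 (median 0.19), and both camera without that tumour and fry with all 8 gave the lower direction without passing. Apart from the smaller samples, the added fold requirement and the wider question of fry, the cause was not tested. The tumour design recovered 7.46% of simulated 2-fold changes, in draws without patterns shared by many genes.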

Other observations

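The test of vismodegib-lowered genes in the tumours was planned before its result was seen, as was leaving out each tumour in turn. Naming genes from the comparison without sensitive tumour 4 was chosen only after the tumours had been seen. Further pathway genes differed between resistant tumours and sensitive tumours 1 to 3. Of 15 TGF-beta targets 6 rose and 1 fell (adjusted p = 0.0538), and Smad7, a feedback inhibitor, rose by 1.65 ± 0.25 on the log2 scale (SE, n = 4 and 3). Of 14 Wnt targets 4 rose and 6 fell (adjusted p = 0.466), and Myc rose by 1.23 ± 0.18 and Bmp4 by 2.48 ± 0.43, while the stem cell receptor Lgr5 (-1.85 ± 0.29) and Nkd1 (-3.56 ± 0.62) fell. Of 9 Notch targets 2 rose and 4 fell (adjusted p = 0.519), and the receptor Notch1 (-0.79 ± 0.19) and its ligand Dll1 (-1.15 ± 0.30) fell and Hes1 (0.67 ± 0.16) rose. Of 20 fibroblast and matrix genes 5 rose and 4 fell (adjusted p = 0.277), and Fn1, fibronectin, rose by 2.89 ± 0.24 and Dpt fell by 3.36 ± 0.64. Of 8 sebaceous gland genes 1 rose and 3 fell (adjusted p = 0.719), and Cidea fell by 4.53 ± 0.62.

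CCG-1423 moved genes of the same pathways in ASZ001 cells. Of 15 TGF-beta targets 10 fell, among them Tgfbi (-2.26 ± 0.03) and Bambi (-2.13 ± 0.07), and 5 rose, and the list did not pass (adjusted p = 0.309). Of 10 Wnt targets 5 rose, among them Axin2 (2.34 ± 0.08), and 4 fell (adjusted p = 0.617). Of 8 Notch targets 6 rose, among them Hes1 (1.71 ± 0.10), and 2 fell (adjusted p = 0.152). Of 13 fibroblast and matrix genes 7 fell and 3 rose (adjusted p = 0.344), and Col6a1 fell by 2.17 ± 0.08, and by 0.51 ± 0.08 with vismodegib. With vismodegib 3 of 10 Wnt targets fell, among them Lef1 (-0.44 ± 0.07), and the list did not pass (adjusted p = 0.0824). Hair follicle progenitor genes went both ways, 3 lower, among them Nfatc1 (-0.48 ± 0.05), and 3 higher, among them Msx2 (0.37 ± 0.06), with adjusted p = 0.923.

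Genes lowered by vismodegib in ASZ001 cells might be higher as a group in resistant tumours, if resistance restored Hedgehog output. In the 8 tumours 493 such genes had a median log2 fold change of 0.11, and camera with an estimated correlation gave a p of 0.253. Without sensitive tumour 4 the median over 495 genes was 0.14 and the p 0.424. The bound set beforehand, a p of 0.05 or more, was wrong, because a p that misses a threshold does not exclude a shift, and fry gave 0.0380 and 0.0260. The hypothesis stays open.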
